A study of Mus musculus with 28 samples.

How the data were processed

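Small RNA was measured on Agilent mouse miRNA microarrays in laser-microdissected tissue from the medial tibial plateau of mice. The mice had undergone destabilization of the medial meniscus (DMM), a surgical model of osteoarthritis in which the joint is made unstable, or a sham operation. Tissue was taken 1 or 6 weeks later. The 28 arrays fell into 8 groups by tissue, operation and week. Each of the 4 cartilage groups held 3 arrays, each of a pool of 3 mice, and each of the 4 subchondral bone groups held 4 arrays of single mice. Operation and week were read from the sample titles, and tissue from the source field. For the cartilage samples another label field names the tissue as bone, while the source field names cartilage and the title names no tissue. miR-140-3p, a miRNA known to be abundant in cartilage, had a mean log2 signal of 13.41 ± 0.19 (SD, n = 12) in the arrays with cartilage in the source field. It had 9.34 ± 0.33 (SD, n = 16) in those with subchondral bone there, and the source field was followed.

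The deposited table holds 569 miRNA rows. Its values were taken as log2 signals from their range, 4.08 to 16.7, and were used as deposited. The submitters' processing notes name limma 3.20.9. The background correction, the normalization and the filter on rows are not given in the sources used here. In the cartilage arrays 438 rows hold a value on every array, in the bone arrays 490, and 359 rows are shared, so a filter had been applied to each tissue apart. Whether both tissues were normalized together is not given in the sources used here, and levels set side by side across tissues carry that limit. Array medians were 6.26 to 6.32 in cartilage and 6.17 to 6.39 in bone. Background and detection values of the scanner were not used here, so the precision of a value rests on the spread between arrays, and the number of arrays limits it. The table had 0 unused columns of sample values.

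Comparisons were fitted with limma 3.58.1 in R 4.3.3, with jsonlite 2.0.0 for reading labels. A group-means model was fitted to all arrays of 1 tissue, with empirical Bayes moderation, and p-values were adjusted by Benjamini-Hochberg over all miRNAs tested in a comparison. The threshold was an adjusted p of 0.05. P-values measure the spread between pools in cartilage and between mice in bone. The 10 comparisons were DMM against sham at each week, the difference of these effects between weeks and sham at 6 weeks against sham at 1 week, all within a tissue, and the difference of the DMM effect between tissues at each week. The last kind was fitted to all 28 arrays over the 359 shared rows. The labels take both tissues from the same mice but do not tie pools to mice, so arrays of both tissues were treated as independent there, and pools and single mice shared 1 estimate of spread. A planned comparison of levels between cartilage and bone in sham mice was not run, because the rows had been filtered per tissue and a shared normalization could not be established.

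The choices in this paragraph were made before the data were examined. For each DMM comparison the text names, among miRNAs past the threshold with a mean above the 25th percentile, the 12 with the largest rise and the 12 with the largest fall. Where fewer than 5 passed in a direction, the 5 with the smallest unadjusted p were taken and are given as not passing. Members of the lists of cartilage-enriched, inflammation-induced, erythroid, hypoxia and miR-34 family miRNAs could always be named, and members of any other list where they passed. For the other comparisons the 5 largest changes in each direction were named. The 20 lists also held miRNAs of haematopoietic, muscle, endothelial, fibroblast or mesenchymal and epithelial (miR-200 family) cells, the miR-29, miR-15/16, miR-17-92, let-7, miR-181 and miR-30 families, the Dlk1-Dio3 cluster, the Sfmbt2 cluster, miRNAs named in osteoarthritis literature, and late-numbered miRNAs. Lists with 3 or more measured members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. For each list the members past the threshold were counted with p adjusted over all miRNAs and adjusted over the list alone. Alternatives were quantile normalization, centring on the 75th percentile, leaving out rows below the median level, a trend and robust prior, array weights, weights per tissue for the comparison between tissues, other sets of arrays in the fit, a replicate block in cartilage, an animal-number block in bone, and leaving out each array in turn.

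The fit was tested on simulated data with independent noise at the spread of these arrays, with 40 changed rows per size in 20 simulations. For cartilage DMM against sham over 438 rows, 95.5% of changes of 1 on the log2 scale were called at 1 week and 95.1% at 6 weeks. For bone DMM against sham over 490 rows, 77.4% of changes of 1 were called at 1 week and 79.4% at 6 weeks, and 97.5% and 98.2% of changes of 2. For the difference between tissues over 359 rows, 66.4% of changes of 1 were called at 1 week and 62.9% at 6 weeks. Between 2.79% and 4.90% of calls were false. Real arrays of a tissue did not vary independently across miRNAs, so these shares describe independent noise.

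Pre-miRNA genes and the genes that contain them were looked up by name in an annotation of the mouse assembly GRCm38.p6, which paired 377 of the 438 cartilage rows with a hairpin gene. Strand was not given in that table, and no coordinates are printed since the assembly behind the array design is not given in the sources used here.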

Results

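miRNA levels were compared between DMM and sham mice in cartilage and in the subchondral bone under it, early (1 week) and later (6 weeks) after surgery. The design addresses which miRNAs differ in each tissue as osteoarthritis starts, and whether the difference persists. Cartilage arrays correlated closely, with a median Pearson correlation across miRNAs of 0.987 within a group and a lowest of 0.967, and a median within-group SD of 0.172 on the log2 scale. Bone arrays varied more, with a median correlation of 0.951 within a group, a lowest of 0.809 and a median SD of 0.333. Cartilage arrays were of pools, which average over mice, and bone arrays of single mice, so these spreads do not compare the tissues alone.

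In cartilage 1 week after DMM, some miRNAs rose severalfold while others fell by less. miR-6931-5p rose most, 6.03-fold, from a mean log2 signal of 8.54 ± 0.13 (SD, n = 3) in sham to 11.14 ± 0.28 (SD, n = 3) in DMM, a log2 fold change of 2.59 ± 0.21 (SE) with an adjusted p of 1.23e-05. miR-1187 rose 3.78-fold, from 8.79 ± 0.12 to 10.71 ± 0.35 (SD, n = 3 each), and miR-574-5p rose 3.54-fold, from 9.75 ± 0.09 to 11.58 ± 0.30 (SD, n = 3 each). miR-3082-5p rose by 1.85, miR-468-3p by 1.48 and miR-32-3p by 1.46 on the log2 scale, with SE between 0.22 and 0.25. The largest falls among the named miRNAs were smaller. miR-196b-5p, encoded in a Hox gene cluster, had a log2 fold change of -0.59 ± 0.11 (SE), from 7.63 ± 0.09 to 7.04 ± 0.12 (SD, n = 3 each), with an adjusted p of 0.00272. miR-374c-5p changed by -0.56, miR-299b-5p by -0.53 and miR-425-5p by -0.51.

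Most miRNAs of the Sfmbt2 list rose, a list of miRNAs of a large rodent cluster in an intron of the Polycomb gene Sfmbt2 and of relatives encoded elsewhere. Of 25 measured members 15 rose and 4 fell, and 15 and 9 when adjusted over the list alone. miR-466i-5p rose by 1.81, from 11.12 ± 0.10 to 12.94 ± 0.25 (SD, n = 3 each), miR-669n by 1.60, miR-669l-5p by 1.31, miR-466m-5p by 1.20 and miR-669e-5p by 1.14 on the log2 scale. The 4 that fell were miR-466i-3p (-0.54), miR-466f-3p (-0.53), miR-669f-3p (-0.53) and miR-466g (-0.48), and for 3 of them, miR-466i-3p, miR-466f-3p and miR-669f-3p, the 5p arm of the same name rose. The median of the list was 0.85 and its camera adjusted p 0.00978, and the adjusted p was 0.401 with an estimated correlation. Among 122 late-numbered miRNAs, which entered miRNA catalogues late and are often near background on arrays, 19 rose and 2 fell, and 18 and 1 when adjusted over the list alone. miR-6348 rose by 1.14 ± 0.24 (SE), and miR-8110 rose by 0.65. The list's camera adjusted p was 0.0158 and 0.401 with an estimated correlation. Its median was 0.08 in the values as deposited and -0.02 after centring on the 75th percentile, so the list as a whole had no direction that held across scalings.

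Some of the falls at 1 week were in the Dlk1-Dio3 cluster and in the let-7 and miR-30 families. The Dlk1-Dio3 cluster lies in an imprinted locus whose miRNAs are expressed from the maternal chromosome. Of its 28 measured miRNAs 13 fell and 0 rose, and 18 fell when adjusted over the list alone. Examples were miR-411-3p (-0.58), miR-376c-3p (-0.53), miR-379-5p (-0.50) and miR-411-5p (-0.49). Its median was -0.39 and its camera adjusted p 1.49e-05, and the adjusted p was 0.401 with an estimated correlation. In the let-7 family, known to repress growth-related mRNAs such as Hmga2, 5 of 9 listed members fell and 7 when adjusted over the list alone. let-7j, outside the list and named after its values were seen, passed as higher at 1 week (0.55) and at 6 weeks (0.47). let-7c-5p fell from 13.77 ± 0.05 to 13.29 ± 0.18 (SD, n = 3 each), and miR-98-5p changed by -0.49, let-7a-5p and let-7b-5p by -0.46 each. Their camera adjusted p was 0.00978, and 0.401 with an estimated correlation. In the miR-30 family 4 of 7 fell and 5 when adjusted over the list alone, led by miR-30c-5p (-0.54 ± 0.14, SE) and miR-30e-3p (-0.47). The camera adjusted p was 0.0101, and 0.401 with an estimated correlation. The medians of these 3 lists and of the Sfmbt2 list kept their sign under quantile normalization and under centring on the 75th percentile, while with a score for the main gradient between bone arrays as a covariate the let-7 median turned to 0.011 and let-7a-5p to 0.025.

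Among cartilage-enriched miRNAs, miR-455-5p, encoded within the collagen gene Col27a1, changed by -0.40 ± 0.13 (SE) with an adjusted p of 0.0457. The other 3 did not pass, with -0.46 for miR-455-3p, -0.27 for miR-140-5p and -0.21 for miR-140-3p. The list had 2 lower when adjusted over the list alone, and a camera adjusted p of 0.0729. In the miR-29 family, listed for members that target collagen mRNAs, the 5p arms miR-29c-5p (-0.37) and miR-29b-1-5p (-0.35) fell out of 5 measured. The same number fell when adjusted over the list alone, with a camera adjusted p of 0.0729. Whether these 5p arms target collagen mRNAs was not tested. In the miR-181 family 2 of 5 fell, miR-181a-1-3p and miR-181c-5p with -0.45 each, and 2 when adjusted over the list alone, also with a camera adjusted p of 0.0729. miR-210-3p, a target of hypoxia-inducible factor, changed by -0.33 ± 0.11 (SE), with an adjusted p of 0.0490, and was the only measured member of the hypoxia list. Of 20 miRNAs from osteoarthritis literature, 1 rose, miR-222-3p (0.52), and 3 fell, miR-149-5p (-0.31), miR-210-3p and miR-411-5p, against 1 and 1 when adjusted over the list alone, with a camera adjusted p of 0.0729. Under quantile normalization, and under centring on the 75th percentile, 1 rose and 6 fell. None of the 5 inflammation-induced miRNAs passed, with p adjusted over all miRNAs or adjusted over the list alone. miR-21a-5p, often raised in inflamed tissue, had 0.80 ± 0.37 (SE) with an adjusted p of 0.118, from 8.69 ± 0.15 to 9.49 ± 0.78 (SD, n = 3 each). miR-212-3p had 0.51, miR-155-5p 0.11, miR-146a-5p -0.17 and miR-146b-5p -0.29, and the list's camera adjusted p was 0.676.

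Markers of other cells did not pass as groups at 1 week. The 2 erythroid miRNAs had a median of -0.08 and the 3 haematopoietic miRNAs a median of -0.11 with a camera adjusted p of 0.638, and none passed, also when adjusted over the list alone. The single endothelial miRNA had 0.09. Of 4 muscle miRNAs, miR-206-3p rose by 0.53 ± 0.13 (SE) while the list's median was -0.75, and of 5 fibroblast or mesenchymal miRNAs miR-214-5p rose by 0.53 while the median was -0.23. Each of these lists had 1 rise when adjusted over the list alone and a camera adjusted p of 0.676. None of 6 miR-15/16, 8 miR-17-92 or 2 miR-34 family members passed, also when adjusted over the list alone, with medians of -0.31, -0.05 and -0.19 and, for the first and second, camera adjusted p of 0.0682 and 0.676. Of the 6 miR-15/16 members, 3 fell after quantile normalization and 2 after centring on the 75th percentile. No miR-200 family member had values in cartilage.

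In all, 122 of 438 miRNAs passed in cartilage at 1 week, 69 higher and 53 lower, by limma at an adjusted p of 0.05, and 15 of them were at least 2-fold higher while 0 were at least 2-fold lower. The split depended on the scaling, with 60 higher and 75 lower after quantile normalization and 56 and 86 after centring on the 75th percentile. The count was 42 without DMM replicate 3 and 56 without sham replicate 3 of that week. It was 54 of 219 tested with rows below the median level left out, and 27, each of them higher, in a fit to all 28 arrays over 359 rows. It was 0, with 10 at an unadjusted p under 0.05, with a gradient score as a covariate, the score of each array on the first component of the deviations of bone arrays from their group means, which in cartilage separated DMM from sham at both weeks. Of the 15 higher and 35 lower miRNAs followed through each fit with 1 array left out, 13 and 7 passed in all 12 fits.

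**Figure D1:**
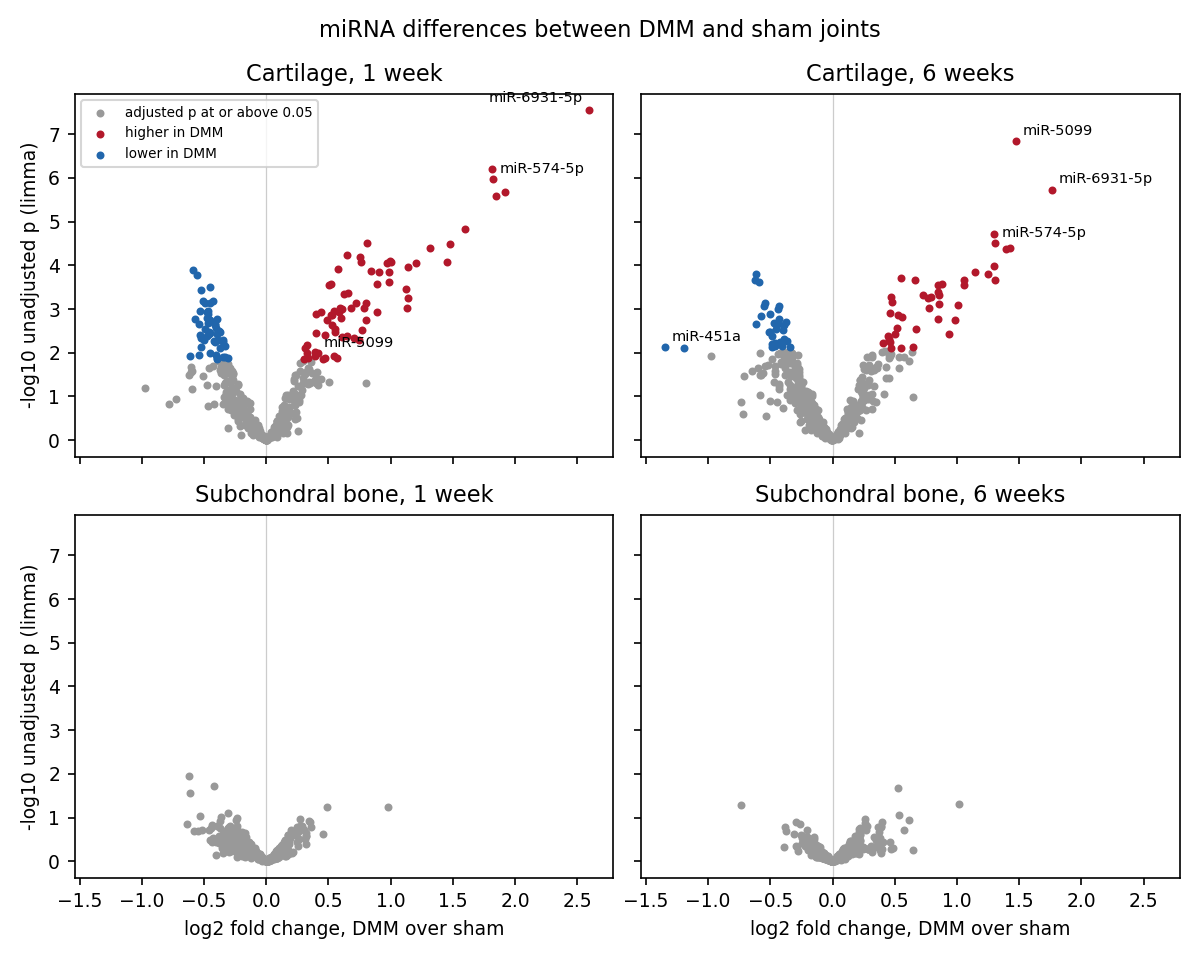
Log2 fold change of DMM over sham (horizontal axis) against -log10 of the unadjusted limma p (vertical axis), 1 point per miRNA, in cartilage and subchondral bone at 1 and 6 weeks. Coloured points, higher (red) or lower (blue) at an adjusted p under 0.05, number 122 and 74 in cartilage and 0 in either bone panel.

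In cartilage 6 weeks after DMM, 41 of the 42 higher miRNAs were ones that were also higher at 1 week, and 4 of 5 blood cell miRNAs were lower. miR-6931-5p rose 3.39-fold, from 8.19 ± 0.37 to 9.95 ± 0.30 (SD, n = 3 each), a log2 fold change of 1.76 ± 0.21 (SE) with an adjusted p of 4.09e-04. miR-5099 rose 2.78-fold, from 5.84 ± 0.07 to 7.32 ± 0.16 (SD, n = 3 each), a log2 fold change of 1.47 ± 0.14 (SE) with an adjusted p of 6.30e-05, and had risen by 0.41 ± 0.14 (SE) at 1 week. miR-1187 rose by 1.42, miR-3082-5p by 1.39, miR-574-5p by 1.30 and miR-32-3p by 1.30 on the log2 scale. Among the falls, miR-107-3p had -0.62 ± 0.11 (SE), from 9.23 ± 0.10 to 8.61 ± 0.19 (SD, n = 3 each), with an adjusted p of 0.00643. miR-210-3p had -0.59 ± 0.11 (SE), from 10.33 ± 0.12 to 9.74 ± 0.16 (SD, n = 3 each), with an adjusted p of 0.00661. miR-100-5p changed by -0.51 and miR-1839-5p by -0.50.

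The calls for blood cell miRNAs in cartilage at 6 weeks depended on single arrays. Of the erythroid list, miR-451a, the most abundant miRNA of red blood cells, had -1.34 ± 0.42 (SE), from 9.13 ± 0.93 in sham to 7.79 ± 0.51 in DMM (SD, n = 3 each), with an adjusted p of 0.0465. miR-486a-5p had -0.50 ± 0.14 (SE) with an adjusted p of 0.0283. Its level was low, with a mean of 5.82 ± 0.27 (SD, n = 12) over the cartilage arrays, below the array medians of 6.26 to 6.32. Of the haematopoietic list, the myeloid miR-223-3p had -1.19 ± 0.37 (SE), from 8.31 ± 0.71 to 7.12 ± 0.45 (SD, n = 3 each), miR-342-3p had -0.57 ± 0.14 (SE), and miR-142a-3p had -0.98 with an adjusted p of 0.0566. Thus 2 of 2 and 2 of 3 fell, and 2 and 3 when adjusted over the list alone. The haematopoietic list's camera adjusted p was 0.0484, and 0.457 with an estimated correlation, and it was 0.114 without DMM 6-week replicate 1. The single endothelial miRNA had -0.74. The calls for miR-451a and miR-223-3p each held under 5 of 21 alternatives. Adjusted p ranged from 0.00407 to 0.634 for miR-451a and from 0.00603 to 0.634 for miR-223-3p. Both calls were lost without any 1 array other than sham 6-week replicate 1 or sham 1-week replicate 3. Leaving out a 1-week array left the fold changes at -1.34 and -1.19, with an adjusted p of at most 0.0645. miR-342-3p lost its call in 7 of 21 alternatives and miR-486a-5p in 7 of 20, among them the fits without DMM 6-week replicate 1 or 2 or sham 6-week replicate 2 or 3, with an adjusted p of up to 0.0864 for miR-342-3p and 0.123 for miR-486a-5p in these fits. Without sham 6-week replicate 3, miR-451a had -0.86 with an adjusted p of 0.145 and miR-223-3p -0.84 with 0.153.

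Members of the Sfmbt2 and Dlk1-Dio3 lists passed at 6 weeks as well. Of the 25 Sfmbt2 list members 15 rose and 0 fell, and 15 and 6 when adjusted over the list alone, with a median of 0.72. miR-466i-5p rose by 1.30, miR-669n by 1.30, miR-669l-5p by 1.14, miR-466m-5p by 1.06 and miR-669e-5p by 1.05. The camera adjusted p was 0.00399, and 0.457 with an estimated correlation. Without sham 6-week replicate 1 it was 0.0547, while the median rose to 0.86. Of the 28 Dlk1-Dio3 miRNAs 11 fell, and 16 when adjusted over the list alone, with a median of -0.39, among them miR-434-3p (-0.62 ± 0.16, SE) and miR-154-5p (-0.49). The camera adjusted p was 1.77e-04, and 0.457 with an estimated correlation. In the miR-15/16 family, known to target cyclin mRNAs, 2 of 6 fell, miR-15a-5p (-0.55 ± 0.12, SE) and miR-15b-5p (-0.54 ± 0.12, SE), and 6 when adjusted over the list alone. The camera adjusted p was 0.00721, and 0.457 with an estimated correlation. The 3p arms miR-15a-3p (0.46), miR-16-1-3p (0.56) and miR-195a-3p (0.77) passed as higher, also at 1 week. They were outside this list and were named after their values were seen. The signs of the Sfmbt2, Dlk1-Dio3 and miR-15/16 medians and of the haematopoietic and erythroid medians held under both other scalings.

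In the let-7 family at 6 weeks let-7d-5p fell (-0.37 ± 0.11, SE) out of 9, and 1 when adjusted over the list alone, with a camera adjusted p of 0.0646. In the miR-30 family 0 of 7 passed and 5 were lower when adjusted over the list alone, with a median of -0.32, a camera adjusted p of 0.0236, and 0.457 with an estimated correlation. miR-210-3p, the only measured member of the hypoxia list, was also the only 1 of the 20 osteoarthritis-literature miRNAs past the threshold at 6 weeks, and 1 passed when adjusted over the list alone, with a camera adjusted p of 0.0646. Of 122 late-numbered miRNAs 8 rose, and 2 when adjusted over the list alone, with a camera adjusted p of 0.0514 and a median of 0.03 that was -0.01 after centring on the 75th percentile. miR-206-3p rose by 0.53 ± 0.13 (SE), alone among 4 muscle miRNAs and also when adjusted over the list alone, with a camera adjusted p of 0.406. None of the 4 cartilage-enriched miRNAs passed, with -0.34 and an adjusted p of 0.0558 for miR-140-3p, -0.30 for miR-140-5p, -0.08 for miR-455-5p and -0.02 for miR-455-3p, and 1 was lower when adjusted over the list alone. Their camera adjusted p was 0.312. None of the 5 inflammation-induced miRNAs passed either way, with 0.65 ± 0.37 (SE) for miR-21a-5p, 0.32 for miR-212-3p, 0.25 for miR-155-5p, -0.03 for miR-146a-5p and -0.22 for miR-146b-5p, and a camera adjusted p of 0.406. The miR-29 (median -0.20, camera adjusted p 0.104), miR-17-92 (-0.20, 0.101), miR-181 (-0.02, but 0.01 after quantile normalization, 0.894) and miR-34 (-0.03) families had no member past the threshold, also when adjusted over the list alone. Fibroblast or mesenchymal miRNAs had 0 of 5 past it, 1 higher and 2 lower when adjusted over the list alone, and a camera adjusted p of 0.588.

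At 6 weeks 74 of 438 miRNAs passed in cartilage by limma, 42 higher and 32 lower, with 13 at least 2-fold higher and 2, miR-451a and miR-223-3p, at least 2-fold lower. The split was 42 and 30 after quantile normalization and 37 and 36 after centring on the 75th percentile. The number depended on single arrays of that week, with 20 without DMM replicate 2, 44 without DMM replicate 1, 27 without sham replicate 2, 31 without sham replicate 3 and 166 without sham replicate 1. It was 40 of 219 tested (25 higher and 15 lower) with rows below the median level left out, and 189 (84 and 105) with array weights. A fit to the 2 groups alone gave 29 (24 and 5), the replicate block 43 (31 and 12) and a fit to all 28 arrays 2 (2 and 0). With the gradient covariate it was 0, with 19 at an unadjusted p under 0.05. Of the 13 higher and 22 lower miRNAs followed through each fit with 1 array left out, 12 and 3 passed in all 12 fits. The 12 higher ones were the 12 largest named rises, among them miR-6931-5p, miR-5099 and miR-1187. The remaining 1, miR-206-3p, passed in 9 of the 12 fits, with a limma adjusted p of up to 0.0815.

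The effects at both weeks in cartilage were alike. Of the miRNAs that passed, 41 were higher at both weeks against 6.62 for independent lists, 16 were lower at both against 3.87, and 0 went in opposite directions. Across 438 miRNAs, which are not independent replicates, the log2 fold changes correlated with a Pearson r of 0.877 and a Spearman rho of 0.859. The weeks shared no sham arrays. The difference of the DMM effect between weeks was tested directly and 0 miRNAs passed by limma, with 13 at an unadjusted p under 0.05. miR-5099, named after its values were seen, had the smallest adjusted p, 0.0565, with a DMM effect larger at 6 weeks by 1.06 ± 0.19 (SE). In other fits 1 miRNA passed with quantile normalization, with array weights or with rows below the median level left out, and 1 without DMM 6-week replicate 3 or without sham 1-week replicate 2.

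**Figure D2:**
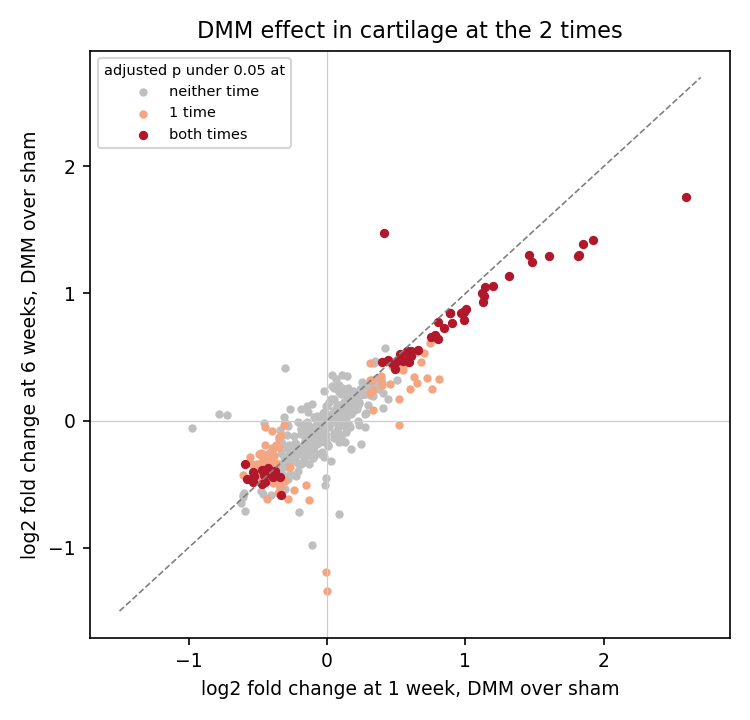
Log2 fold change of DMM over sham in cartilage at 1 week (horizontal axis) against that at 6 weeks (vertical axis), 1 point per miRNA, coloured by whether the adjusted p was under 0.05 at both weeks in the same direction, at 1 of them or at neither, with a dashed line of equal change. The points follow a line of slope 0.792 with a Pearson correlation of 0.877 across 438 miRNAs, and 41 miRNAs were higher and 16 lower at both weeks.

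Between the sham groups of cartilage, miR-1957b was higher at 6 weeks than at 1 week, 6.35 ± 0.06 against 5.78 ± 0.07 (SD, n = 3 each), a log2 fold change of 0.56 ± 0.09 (SE) with an adjusted p of 0.0269. It was the 1 miRNA past the threshold by limma among 438, with 77 at an unadjusted p under 0.05. The erythroid and haematopoietic miRNAs together had a median change of 0.83 between these sham groups. The count was 9 without sham 6-week replicate 1, 2 without DMM 6-week replicate 3, 68 with array weights, and 0 without any 1 of sham 1-week replicates 1, 2 and 3, DMM 1-week replicate 3, DMM 6-week replicate 2 or sham 6-week replicate 3. It was also 0 with rows below the median level left out, in fits to the 2 groups alone or to all 28 arrays, and with the gradient covariate.

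In subchondral bone no miRNA differed detectably between DMM and sham at 1 week. miR-5100 had 0.49, miR-181b-5p 0.36, miR-7047-3p 0.34, miR-574-3p 0.27 and miR-207 0.27 on the log2 scale, the smallest p-values among those higher in DMM with a mean level above the 25th percentile, and none passed. On the lower side were miR-142a-3p (-0.64), miR-223-3p (-0.53), miR-652-3p (-0.42), miR-1904 (-0.24) and miR-3473g (-0.24), none past the threshold. The miRNAs that rose most in cartilage were near 0 here, with 0.18 ± 0.18 (SE) for miR-6931-5p, 8.18 ± 0.17 in DMM against 8.00 ± 0.33 in sham (SD, n = 4 each). By limma 0 of 490 miRNAs passed, the smallest adjusted p was 0.999, and 3 had an unadjusted p under 0.05. Array weights called 38, though that estimate stopped before its tolerance.

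The lists in bone at 1 week had 0 members past the threshold, also when adjusted over the list alone. The 6 haematopoietic miRNAs had a median of -0.36 with a camera adjusted p of 0.0310, and the 14 members of the miR-17-92 clusters a median of -0.22 with 0.0384. With an estimated correlation both had an adjusted p of 0.857. Each call was lost in 6 of 16 fits with 1 array left out, with an adjusted p of up to 0.224 for the haematopoietic list, without sham 1-week replicate 3, and of 0.867 with a median of 0.05 for the miR-17-92 clusters, without sham 1-week replicate 4. None of the other tested lists passed, the smallest camera adjusted p being 0.0563, shared by the Sfmbt2 list (32 measured, median 0.04) and the miR-181 family (5 measured, median 0.09). The cartilage-enriched miRNAs had -0.19 for miR-140-3p, -0.38 for miR-140-5p and 0.05 for miR-455-3p. The camera direction opposed the sign of the median for the osteoarthritis-literature and late-numbered lists at 1 week and for the erythroid and miR-181 lists at 6 weeks. At 1 week the inflammation-induced list had a median of -0.19 and the 5 erythroid miRNAs a median of -0.23.

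At 6 weeks the bone again showed no detectable difference. Above the 25th percentile of mean level, the smallest p-values were those of miR-6929-3p (0.62), miR-6984-3p (0.54), miR-7068-5p (0.40), miR-652-5p (0.39) and miR-6368 (0.26) on the higher side, and of miR-5099 (-0.29), miR-6971-5p (-0.26), miR-155-5p (-0.25), miR-1231-5p (-0.20) and miR-8102 (-0.15) on the lower side, none past the threshold. By limma 0 of 490 passed, with 2 at an unadjusted p under 0.05 and a smallest adjusted p of 0.998. Array weights called 54, with the same limit. No list member passed, also when adjusted over the list alone, and the smallest camera adjusted p of a list was 0.375, for the Sfmbt2 list with a median of 0.12. The Dlk1-Dio3 list (6 measured) had a median of 0.16, and medians of all other lists in bone at 6 weeks lay between -0.16 and 0.12.

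The weeks were less alike in bone than in cartilage, with a Pearson r of 0.374 and a Spearman rho of 0.422 across 490 miRNAs. The correlation ranged from -0.0186 without sham 1-week replicate 4 to 0.547 without sham 1-week replicate 1. For the difference of the DMM effect between weeks in bone 0 miRNAs passed by limma, with 1 at an unadjusted p under 0.05. Between the sham groups at 6 and 1 weeks 0 passed, with 54 at an unadjusted p under 0.05 and a smallest adjusted p of 0.414. That count was 5 without sham 1-week replicate 1, 140 with array weights and 65 with the gradient covariate. In bone, centring on the 75th percentile moved the median log2 fold change of all miRNAs at 1 week from -0.06 to 0.08, so signs of small changes there depend on the scaling. The difference between weeks moved from 0.08 to -0.10 and the sham comparison from -0.09 to 0.03. At 1 week the medians of the let-7, miR-34, osteoarthritis-literature, endothelial and late-numbered lists, and at 6 weeks that of the erythroid list, changed sign with the scaling.

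The DMM effect differed between tissues for a pair of miRNAs. At 1 week the rise of miR-6931-5p was larger in cartilage than in bone by 2.41 ± 0.28 (SE) on the log2 scale, with an adjusted p of 3.28e-06. At 6 weeks it was larger by 1.70 ± 0.28 (SE), with an adjusted p of 5.66e-04, and that of miR-5099 by 1.77 ± 0.24 (SE), with an adjusted p of 5.18e-05. In bone at 6 weeks, miR-5099 was 5.92 ± 0.33 in DMM and 6.22 ± 0.33 in sham, and miR-6931-5p 8.19 ± 0.21 and 8.13 ± 0.22 (SD, n = 4 each). By limma 1 of 359 shared miRNAs passed at 1 week and 2 at 6 weeks, with 59 and 13 at an unadjusted p under 0.05. The tissues came from the same mice but the pools could not be tied to them, so the arrays were treated as independent and the p-values leave out any shared animal, and tissue was confounded with pooling. Array weights called 52 and 32, from an estimate that stopped before its tolerance, while weights per tissue called 1 and 2. With other settings 1 passed at 6 weeks with rows below the median level left out, and centring on the 75th percentile moved the median of all miRNAs at 1 week from 0.10 to -0.09.

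**Figure D3:**
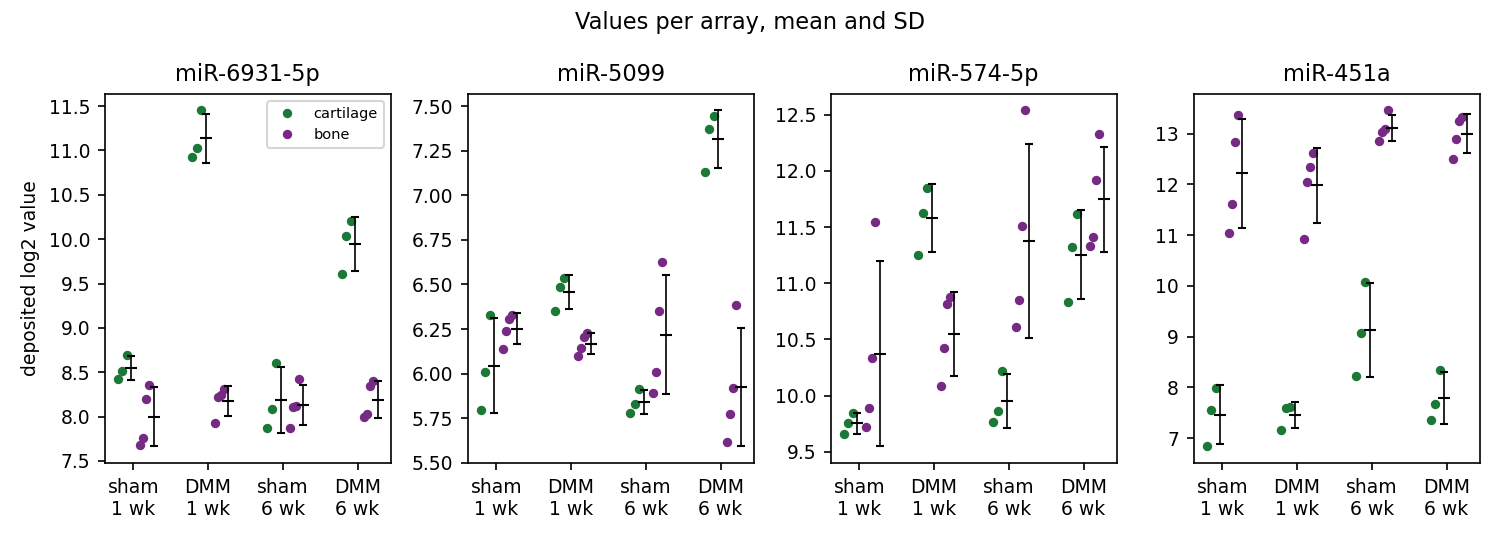
Deposited log2 values of single arrays (points, vertical axis) of miR-6931-5p, miR-5099, miR-574-5p and miR-451a by operation and week (horizontal axis), in cartilage (green, n = 3) and bone (purple, n = 4), with the group mean and SD in black. In cartilage at 1 week miR-6931-5p averaged 11.14 in DMM and 8.54 in sham, while in bone it averaged 8.18 and 8.00.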

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

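The tests of technical explanations in this part were chosen only after the results were seen, while the splits of the samples were planned. Of 54 groups of 4 arrays checked for an array far from the others, 2 stood out, against 2.7 by chance. Among bone sham arrays at 6 weeks, replicate 4 had a median correlation of 0.957 with the other arrays of its group, while the others had 0.939 to 0.941. In the same group, miR-6368 was 9.11 in replicate 2 and 9.26 to 9.28 in the others. The DMM effect differed between cartilage and bone by 2.41 for miR-6931-5p at 1 week, by 1.77 for miR-5099 at 6 weeks and by 1.70 for miR-6931-5p at 6 weeks. Among 100 splits drawn, 8 gave at least the real 1 miRNA at 1 week and 18 at least the real 2 at 6 weeks, with up to 24 and 91 in other splits. Labels were shuffled within each tissue, and the cartilage arrays of a week have only 10 splits, so some draws keep the real cartilage groups. A share under 0.05 could thus hardly be reached, and these shares do not decide on chance, which is not excluded. The high counts point to a structure among the samples.

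The rise of 41 miRNAs in DMM cartilage at both weeks had a median log2 fold change of 0.89 at 1 week and 0.85 at 6 weeks, against 0.04 and 0.16 for the 39 of them measured in bone. A gradient between arrays, the first component of bone deviations from group means with 59.5% of their variance, stays open as a cause. Its 20 highest-loading miRNAs had a median of 0.13 in cartilage at 1 week and -0.01 at 6 weeks, but they went both ways, with an SD of 0.82 and 0.70, so these medians do not decide. A first bound of 0.44 and 0.42 for these medians was passed by 2 SE (0.23 and 0.20 per SE) only at 6 weeks, and the bound was changed more than once after the values were seen. Loading and fold change correlated with 0.497 at 1 week. As a covariate it ended every call of the DMM comparisons in cartilage. Most fold changes of named miRNAs moved towards 0 and the SE grew, while for some, such as miR-210-3p at 6 weeks (-0.59 ± 0.11 to -0.72 ± 0.20, SE), the fold change grew and the call was lost through the SE alone. The median of the 41 went from 0.89 to 0.46 at 1 week and from 0.85 to 0.44 at 6 weeks, and their median SE from 0.17 to 0.33 and 0.27. miR-1187 went from 1.92 to 1.00, miR-574-5p from 1.82 to 0.93 and miR-669e-5p from 1.14 to 0.46 at 1 week, while miR-6931-5p at 1 week (2.59 ± 0.21 to 1.76 ± 0.36, SE) and miR-5099 at 6 weeks (1.47 ± 0.14 to 1.32 ± 0.24, SE) fell by a smaller share. The scores separate DMM (2.37 to 3.72) from sham (-1.37 to -0.776) at 1 week, and DMM (-1.34 to 1.61) from sham (-2.88 to -2.03) at 6 weeks. They are sums over the same cartilage values, the 39 included, so the covariate holds part of the DMM effect itself, and the loss of calls with it decides nothing about the gradient. Marrow, or bone with the blood cells it held on the bone arrays, would raise blood cell miRNAs in DMM cartilage. The higher of their medians over both weeks was -0.11, at 1 week, with a median SE of 0.33, which argues against it. At 6 weeks the median of -0.98 says less, as sham levels were higher than at 1 week by a median of 0.83. Bone free of blood cells was not tested. Deviations of the 41 from group means correlated with a median of 0.852 in cartilage, against at most 0.130 in 1000 random sets. In bone, where no miRNA passed between DMM and sham, those of the 39 correlated with a median of 0.826. These miRNAs thus varied together between arrays also where no DMM effect was detected. A signal shared between probes may contribute, but the correlation does not tell it from the gradient or from miRNAs that vary together in the tissue. An effect of surgery on the tissue stays open beside these.

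The lack of calls in bone was weighed against a hidden difference. With the gradient as a covariate the count stayed 0 at both weeks, with 15 and 7 at an unadjusted p under 0.05 by limma. The same covariate took the sham comparison between weeks from 0 to 65 through the SE alone, as fold changes stayed the same. Any gradient difference between those sham groups was left in, so the 65 do not measure what the covariate can reveal. With the animal numbers as a block it was 0 at both weeks, with 6 and 2 at an unadjusted p under 0.05. By construction the score is centred in each group, so it lowered the median SE from 0.231 to 0.162 and left every fold change as it was. The counts thus argue only against spread within groups along the gradient as the whole cause. A shift of group means along it was not removed and stays open. A batch that follows the animal numbers stays open, since the numbers took 28.1% of the variance within groups and 28 of 324 balanced assignments of arrays took at least as much, so the block was no clear test of it. A difference smaller than the spread between mice, or none, stays open as well, and array weights called 38 and 54. Each bone array was of a single mouse and each cartilage array of a pool of 3 mice, so the counts of the tissues do not compare on equal terms. The splits of the bone arrays decide nothing here, since each of the 35 gives at least the real 0 by construction, with up to 3 in other splits.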

How the results depend on the processing

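All alternatives were planned except the array gradient covariate and leaving out bone sham 1-week replicates 1 and 4 together, which were chosen after seeing the data; another, without 2 cartilage sham 6-week arrays, was run once and dropped because its arrays were chosen by outcome. Not run were the log2 offset, since values were already log2, the cartilage against bone comparison in sham mice, and the animal-number block for sham bone between weeks, whose numbers lie within a week.

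For cartilage at 1 week (122) the count was 54 with rows below the median level left out (219 tested), 27 with all 28 arrays (359 tested), 0 with the gradient covariate and 42 to 141 with 1 array left out. At 6 weeks (74) it was 40, 2 and 0, 189 with array weights, 29 with only the 2 groups, and 20 to 166. The replicate block gave 93 at 1 week, 43 at 6 weeks and 0 for sham between weeks, and the numbers do not pair the arrays: 18 same-number pairs had correlations of -0.487 to 0.443 and 1 of 12 arrays correlated best with its own number. For the difference between weeks (0) it was 1 with quantile normalization, 1 with low rows left out, 1 with array weights and 0 to 1. For sham cartilage (1) it was 0 with low rows left out, all 28 arrays, only the 2 groups and the gradient covariate, 68 with array weights, and 0 to 9.

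Array weights, whose estimate stopped before its tolerance in the bone and 28-array fits, gave 38 and 54 in bone at 1 and 6 weeks (0 and 0), 140 in sham bone (0; 65 with the gradient covariate; 0 to 5) and 52 and 32 between tissues (1 and 2). With 1 array left out the bone counts were 0 to 0 at 1 week, 0 to 0 at 6 weeks and 0 to 0 for their difference, and those between tissues 1 to 1 and 2 to 2, the latter 1 with low rows left out. The correlation of effects was 0.811 to 0.902 in cartilage and -0.0186 to 0.547 in bone. Without bone sham 1-week replicates 1 and 4, 0 passed by limma at 1 week, with 0 at an unadjusted p under 0.05.

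With the gradient covariate signs turned at 1 week for miR-140-3p (0.10), miR-140-5p (0.24), miR-455-3p (0.15), miR-146a-5p (0.73), miR-146b-5p (0.25), miR-451a (0.39), miR-34a-5p (0.19), let-7a-5p (0.025), let-7f-5p (0.011), the let-7 median (0.011) and the late-numbered median (-0.051), and at 6 weeks for miR-140-5p (0.087), miR-455-3p (0.44), miR-455-5p (0.034), miR-146a-5p (0.65), miR-146b-5p (0.19) and miR-34a-5p (0.16). With 1 array left out values ranged across 0 from -0.31 to 0.27 for miR-451a at 1 week, where 3 arrays turned the sign, at 6 weeks from -0.23 to 0.10 for miR-455-3p (0.054 with quantile normalization), from -0.15 to 0.0060 for miR-455-5p and from -0.26 to 0.14 for miR-146a-5p, and in bone from -0.40 to 0.052 for the miR-17-92 median at 1 week. miR-5099 in bone at 6 weeks turned with array weights (0.061). The cause was not tested, except that fewer miRNAs or arrays entered the low-row, 2-group and leave-one-out fits. The 28-array fit held fewer miRNAs and shared its spread with bone. There miR-486a-5p in cartilage at 6 weeks kept its fold change while its SE went from 0.138 to 0.302, and that of miR-223-3p from 0.373 to 0.376. Over all alternatives, with the reversed values counted in, named miRNAs kept direction and call in 1029 of 1258 cases at 1 week and 719 of 939 at 6 weeks in cartilage. Lists stayed on the same side of the threshold in 1271 of 1396 cases. Lists past it in neither fit count among these even where their direction changed, so this share does not measure kept direction. The precision of single values is limited by the number of arrays, as signal over background was not used here.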

Other observations

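The tests of blood cell miRNAs in this part were chosen only after the results were seen, and the bound for a single sham array was made stricter after its value was seen, while the splits of the samples were planned. Of the 41 miRNAs higher in DMM cartilage at both weeks, 36 were paired with a hairpin gene and 7 of these lay within Sfmbt2, a Polycomb-group gene. Others lay within other genes, miR-574-5p within Fam114a1 and Tlr6, miR-6931-5p within Dcakd, miR-32-3p within Tmem245, miR-466i-5p within Cdk13 and miR-669n within Slc30a7. The Sfmbt2 list of 25 measured miRNAs held 18 paired with a hairpin gene, of which 10 lay within Sfmbt2. Whether related probes read a rise at 1 locus was not tested. Sham levels of markers differed between the tissues as measured, with the limit that both may have been normalized apart: miR-451a averaged 8.29 ± 1.15 (SD, n = 6) in sham cartilage and 12.67 ± 0.87 (SD, n = 8) in sham bone, miR-223-3p 7.89 and 12.94, and miR-140-5p 12.09 and 8.33.

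Of the 5 erythroid and haematopoietic miRNAs 4 passed as lower in DMM than sham cartilage at 6 weeks, and the 5 had a median of -0.98. A candidate explanation is a rise of blood RNA in the sham group: their median change from 1 to 6 weeks was 0.83 in sham and 0.06 in DMM. These changes use the same 6-week arrays as the -0.98, so they are not independent of it. Between the sham groups 0 of the 5 passed as higher. A single sham array with more blood RNA stays open, since the median was -1.36, -1.08 and -0.56 without sham replicates 1, 2 and 3, and the bound for this explanation was -0.49 with a median SE of 0.33. miR-451a was 8.23, 9.07 and 10.09 in the 3 sham arrays at 6 weeks and 7.35, 8.35 and 7.67 in the DMM arrays. A change in blood supply or marrow exposure with surgery stays open and was not tested.

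The splits of the samples bear on the counts in cartilage and bone. In cartilage, 1 of 10 splits gave as many as the real 122 miRNAs at 1 week, with 0 as the highest other count, and 1 of 10 as many as the real 74 at 6 weeks, with 29 as the highest other. For sham cartilage between weeks 2 of 10 splits gave the real 1, with 1 as the highest other. With 10 splits a share under 0.05 cannot be reached in these 3 comparisons. For the difference between weeks all 100 splits drawn gave at least the real 0 in cartilage, with up to 24, and in bone, with up to 199. For sham bone between weeks all 35 splits gave at least the real 0, with up to 135. Where the real count is 0 every split gives at least as many by construction, so these splits say nothing about chance, while counts of 199 and 135 in other splits point to a structure among the bone arrays.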
